A study of Mus musculus with 24 samples.

How the data were processed

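Polyadenylated RNA from mouse quadriceps (C57BL/6 background) was sequenced in 24 libraries, 1 per mouse, in 9 groups of 3 genotypes. The genotypes were WT, delEx44 and corrected delEx44. The delEx44 mouse lacks exon 44 of Dmd, the dystrophin gene, and is a model of Duchenne muscular dystrophy. Corrected mice were delEx44 mice injected on postnatal day 4 with AAV9 vectors for a single guide RNA and for SpCas9. Each genotype had 3 libraries at 4 weeks (sedentary), 2 at 8 weeks after 1 month of downhill running and 3 at 18 months (sedentary). Per the labels, muscle was frozen in liquid nitrogen, RNA was extracted with a miRNeasy kit and libraries were made with the TruSeq RNA kit.

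Raw read counts per gene were deposited by the authors in 2 tables, one for the 4-week and run groups (15 libraries) and one for 18 months (9 libraries). Per the labels' processing notes, the tools were Trim Galore, Bowtie2 2.3.4.3, STAR 2.7.2b, SAMtools 1.9, HTSeq and edgeR with the mm10 genome. Which aligner made the counts, the gene annotation and the strand setting of the counting are not given in the sources used here. Antisense or overlapping genes therefore cannot be separated, and genes with near-identical copies (Ces1d and Ces1f, Mt1 and Mt2, Ms4a6c and Ms4a6d, Tgtp1, Gbp4 and Chil3 among those named) are uncertain. Both tables hold 24062 gene symbols and 5 records that name no gene. These 5 records were left out; they held 27.4% to 34.2% of the records per library in the first table and 42.2% to 48.3% at 18 months. The 18-month WT columns could be matched to their group, while 2 of them could be matched to a replicate only by column order.

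Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the groups, libraries were scaled with TMM, and a quasi-likelihood model with robust dispersion and 1 mean per group was fitted. The quasi-likelihood F-test gave p-values, adjusted over genes by the Benjamini-Hochberg method, with 0.05 as the threshold. A gene is said to rise, fall or change only if it passed that threshold. All 15 libraries of the first table entered 1 fit (15013 genes), the 9 libraries at 18 months another (14337 genes), and the 18 sedentary libraries 1 more (14937 genes) for differences between ages. Levels are CPM, the counts of a gene scaled to a common library size with TMM factors, with the SD between libraries. Fold changes are log2 values with standard errors (SE) from the fit.

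There were 16 comparisons. The 3 genotypes were compared in pairs at each stage, the run group was compared with the 4-week group in each genotype, and 4 interaction contrasts tested whether a genotype difference changed with running or with age. Running and the step from 4 to 8 weeks of age came together in every genotype, so they cannot be told apart. The 18-month corrected mice received other vector doses (2.5e14 vg/kg for the guide RNA and 5e13 vg/kg for Cas9, against 8e13 vg/kg of each) and a single-stranded in place of a self-complementary guide RNA vector, so age, dose and vector type cannot be separated in the corrected group.

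Gene lists were fixed before the data were examined, as were the design, the rule for named genes and the alternatives listed here unless stated otherwise. Of 626 genes in 32 lists, 610 were in the tables, 604 under the same symbol and 6 under an older one (among them Mymk, Mymx, Ccn2, Adgre1 and Jchain as Tmem8c, Gm7325, Ctgf, Emr1 and Igj). The mitochondrially encoded list had 0 genes in the tables and the sex-linked list had 4, fewer than the 5 needed, so 30 lists were tested. The test was camera of limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 30 lists, which compares a list with all other genes. Its alternatives were the correlation estimated per list and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes. Counts of list members that passed are given over all genes and adjusted over the list alone. A list level is the mean log2 CPM of its members, with a prior count of 2.

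The genes named were chosen by rule. The rule took Dmd and Utrn in every group. For each genotype comparison it took the 6 largest rises and the 6 largest falls among genes that passed, had a mean of at least 5 CPM in 1 of the groups and had no overlap between the libraries of the groups. It also took up to 4 members with the smallest p of each list that camera called, and 1 of a list that it did not call. For running and interaction contrasts it took the 6 smallest p-values in each direction. Predicted genes and unnamed identifiers were counted but not named. Positions come from GENCODE vM21 on GRCm38, where 457 of 462 named symbols matched once.

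Corrected and delEx44 at 1 stage share the delEx44 libraries with delEx44 against WT. The share of genes with opposite signs was therefore set beside 20 simulations without effects, and the 200 genes with the smallest p in each direction of 1 table were tested in the other table, whose mice are different. Other splits of the libraries into 3 and 3 (10 in all) and 50 regroupings for each age interaction were fitted as well.

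The steps were tested on simulated data, with 200 genes changed by known folds. For delEx44 against WT at 4 weeks (14769 genes), 57.1% of 1.5-fold, 73.1% of 2-fold and 85.9% of 4-fold changes were called. After running (14754 genes) the shares were 24.6%, 68.7% and 92.4%, and at 18 months (14190 genes) 38.5%, 78.5% and 95.5%. For the age interaction (14649 genes) they were 13.8%, 52.3% and 82.8%. Of the calls, 2.78%, 3.91%, 4.79% and 3.03% were unchanged genes, and 0 of 30 unchanged lists were called in each. The simulated genes varied independently, while real lists were correlated (estimated at 0.87 for oxidative phosphorylation in delEx44 against WT at 4 weeks). The simulated lists therefore cannot show how often the preset correlation gives false calls in real lists.

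The alternatives were the Wald test of DESeq2 1.42.0, limma-voom, RLE in place of TMM scaling, no low-count filter, a stricter filter (1 CPM), TMM without genes over 1% of the counts, a fit of only the groups compared, each replicate left out in turn, a replicate block for the 18-month groups, and signatures of 100 and 50 genes. Chosen after seeing the data were a covariate for bone and marrow transcripts, a fit without the 2 WT libraries that stand apart (4-week replicate 3 and run replicate 1), a covariate for slow fibre genes at 18 months, and leaving out Rn45s, a ribosomal RNA gene with 0.755% to 6.19% of the counts at 18 months and 0.102% to 0.324% in the first table. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.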

Results

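Quadriceps muscle was sequenced from WT mice, from delEx44 mice, which lack exon 44 of Dmd, and from delEx44 mice given AAV9 vectors for a guide RNA and Cas9 on postnatal day 4 (corrected). At 4 weeks and at 18 months each genotype had 3 sedentary mice, and at 8 weeks, after 1 month of downhill running, each had 2. Counts assigned to genes, in mega-counts (M), were 36.4, 30.6 and 36.7 in the 4-week WT replicates 1 to 3, 38.1, 37.2 and 36.2 in delEx44 and 37.9, 36.2 and 33.3 in corrected muscle. After running they were 34.3 and 37.5 in WT, 35.8 and 34.4 in delEx44, and 34.5 and 35.4 in corrected replicates 1 and 3. At 18 months they were 30.8, 31.3 and 23.1 in WT, 28.4, 28 and 26.5 in delEx44, and 27.7, 27.1 and 28.6 in corrected muscle. Levels are group means, given with the SD between libraries for the leading genes, and log2 fold changes are given with the SE for the leading genes. The genes named as the largest changes of a genotype comparison had no overlap between the libraries of the groups, so every sample showed the direction given. Where counts were few, as for Slc4a1 and Hapln1 at 4 weeks, this rested on a few reads and on the scaling.

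Dmd encodes dystrophin, which joins the cytoskeleton of the fibre to the membrane complex. The gene lies on chromosome X at 82948870 to 85206141 of GRCm38 (plus strand), and exon 44 of the 79-exon transcript Dmd-203 at 84022265 to 84022412. That exon is 148 bases long, which leaves a remainder of 1 on division by 3, so its loss shifts the reading frame. A count over the whole gene does not show whether exon 44 is present, so the genotype of each library rests on its label. In 4-week muscle Dmd stood at 217 ± 19.8 CPM in WT, 39.7 ± 3.14 in delEx44 (18.3% of WT) and 161 ± 9.39 in corrected mice (74.1%; n = 3 each). After running the levels were 154 ± 8.29, 41.3 ± 0.813 (26.8%) and 92.1 ± 4.76 CPM (59.8%; n = 2 each). At 18 months they were 371 ± 47.8, 85.7 ± 1.31 (23.1%) and 235 ± 60.3 CPM (63.3%; n = 3 each), and the 3 corrected libraries had 205, 304 and 195 CPM. Levels of the 2 tables come from separate scalings, and the ages are compared only through interactions.

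Dmd was lower in delEx44 than in WT at 4 weeks (log2 −2.45 ± 0.083, adjusted p = 2.8e-09), after running (−1.9 ± 0.1, adjusted p = 4.2e-07) and at 18 months (−2.11 ± 0.17, adjusted p = 2.2e-05). It was higher in corrected than in delEx44 muscle at 4 weeks (2.02 ± 0.082, adjusted p = 2.9e-08), after running (1.16 ± 0.099, adjusted p = 3.8e-05) and at 18 months (1.45 ± 0.16, adjusted p = 2e-04). Against WT, corrected muscle was at −0.43 ± 0.079 at 4 weeks (adjusted p = 0.12), −0.74 ± 0.097 after running (adjusted p = 0.025) and −0.66 ± 0.16 at 18 months (adjusted p = 0.051). Utrn, which encodes the dystrophin relative utrophin (chromosome 10, 12382188 to 12869365, minus strand), stood at 70.6 ± 3.82, 67.3 ± 5.92 and 70.4 ± 3.33 CPM in WT, delEx44 and corrected muscle at 4 weeks. After running it was at 66.5 ± 5.79, 71.7 ± 3.35 and 60.1 ± 0.244 CPM, and no pair passed at these stages. At 18 months Utrn was at 126 ± 4.11, 157 ± 8.17 and 133 ± 5.43 CPM, higher in delEx44 than in WT (0.32 ± 0.063, adjusted p = 0.0019) and lower in corrected than in delEx44 muscle (−0.24 ± 0.063, adjusted p = 0.012).

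**Figure D1:**
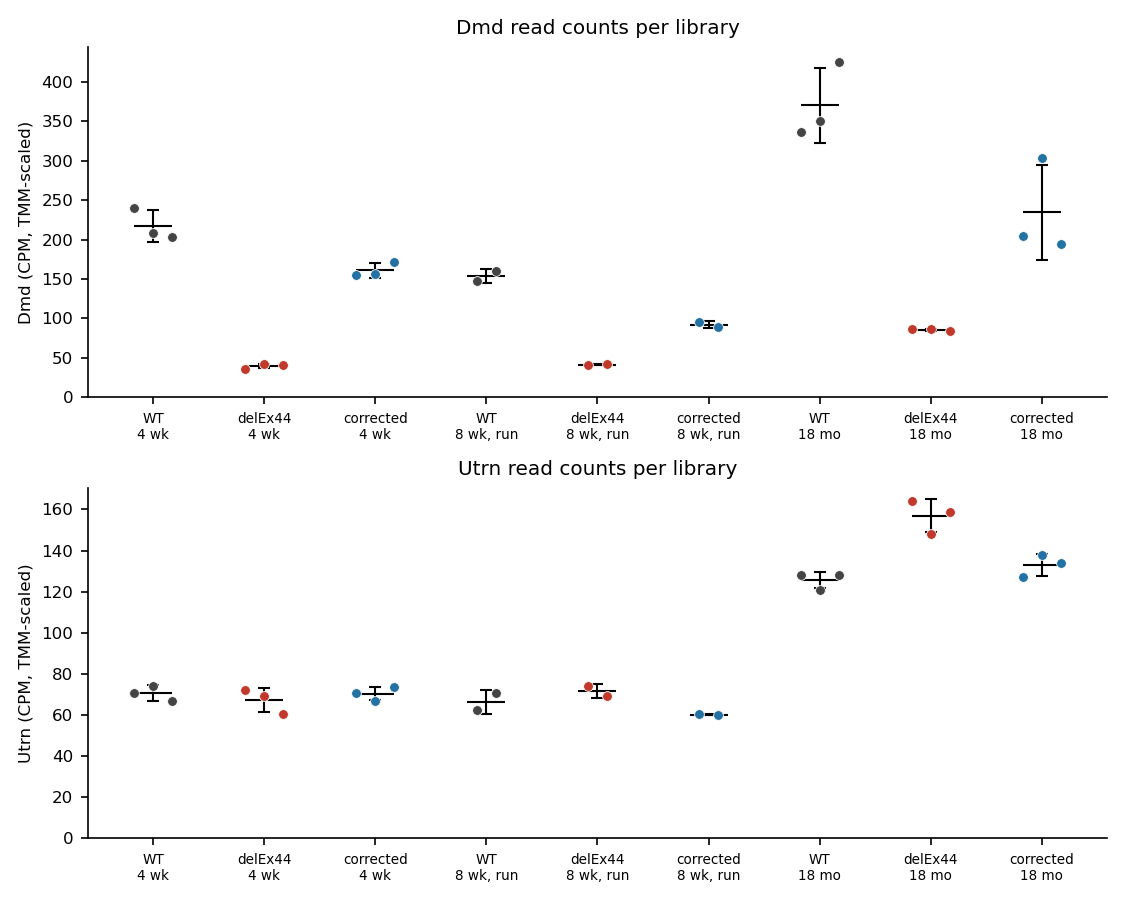
Dmd and Utrn in every library (points) with group means and SD. Dmd in delEx44 was at 18.3%, 26.8% and 23.1% of WT at 4 weeks, after running and at 18 months.

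Sedentary delEx44 muscle at 4 weeks was rich in macrophage and young-fibre transcripts. Mmp12, which encodes the macrophage metalloelastase (chromosome 9, 7344381 to 7369499, plus strand), was at 35.5 ± 8.06 CPM against 0.206 ± 0.0477 in WT (log2 7.42 ± 0.46, adjusted p = 9.4e-07). Myh3, the embryonic myosin heavy chain (chromosome 11, 67078300 to 67102291), was at 265 ± 149 against 3.13 ± 0.496 CPM (6.40 ± 0.45, adjusted p = 2.6e-06). Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose to 216 ± 20.7 from 5.36 ± 1.29 CPM (5.32 ± 0.34), the phagocyte receptor Trem2 to 30.4 ± 6.23 from 0.963 (4.97 ± 0.26), the G-protein regulator Rgs1 to 5.38 from 0.117 (5.47) and the interleukin-1 antagonist Il1rn to 14.8 from 0.429 (5.05 ± 0.52; n = 3 each). The phosphatase inhibitor Ppp1r1a fell to 6.27 ± 1.78 from 44 ± 7.92 CPM (−2.81 ± 0.18), the zinc transporter Slc30a2 to 1.65 from 13.5 ± 4.28 (−3.04 ± 0.47) and the laminin chain Lamc3 to 0.968 from 5.93 ± 0.89 (−2.61 ± 0.29). Slc4a1, the red cell anion exchanger (−6.70 ± 2, adjusted p = 0.021), Hapln1, a cartilage link protein (−4.40 ± 1.3, adjusted p = 0.017), and Scd1, a fatty acid desaturase (56.9 ± 24.6 against 843 ± 891 CPM, −3.89 ± 0.9, adjusted p = 0.0054), also fell. Slc4a1 had 5, 10 and 1037 counts in WT replicates 1 to 3 against 6, 5 and 2 in delEx44. Hapln1 had 17, 11 and 597 against 18, 11 and 10. Each of these genes was lost without delEx44 replicate 1, 2 or 3. Slc4a1 was at 30.8 CPM in WT replicate 3, and neither Slc4a1 nor Hapln1 passed without that library. Scd1 was at 1870 CPM there against 354 and 304 in the other WT libraries, and without it Scd1 was at −2.53 (adjusted p = 0.014, with 6e-06 to 0.032 over 14 other fits).

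Of 27 macrophage and monocyte genes 26 rose, such as Lyz2 (787 ± 200 against 120 ± 14.7 CPM, 2.71 ± 0.18) and Tyrobp (76.4 ± 15.2 against 9.84 ± 1.73, 2.95), with a median log2 of 2.88. All 18 antigen presentation genes rose (H2-Aa 2.32 ± 0.17, Cd74 2.14; median 1.54), as did all 28 interferon response genes (Mx1 3.21, Oasl1 2.49; median 1.39) and 19 of 24 chemokines (Ccl8 3.03, Cxcl16 2.37; median 2.21). Among 21 genes of regenerating and immature fibres 19 rose and 1 fell (20 and 1 when adjusted over the list alone), including Myh8 (177 ± 79.3 against 10 ± 1.41 CPM, 4.14 ± 0.33) and Igf2 (1.89). Of 28 cell cycle genes 24 rose (Ccnb1 1.54, Mcm6 1.16), of 35 collagen and matrix genes 23 rose (Postn 2.41 ± 0.28, Lum 1.11), and of 17 T, B and natural killer cell genes 10 rose and 2 fell (Klrk1 2.88). Of 20 neuromuscular junction and denervation genes (junction genes below) 9 rose, among them the fetal acetylcholine receptor subunit Chrng (4.26 ± 0.4), and 3 fell. Chrng is also in the regenerating fibre list, so these lists are not independent, and whole muscle does not show where in the fibre a transcript lay. These lists were higher in delEx44 than other genes were, at adjusted p between 1.2e-39 for macrophages and 0.019 for lymphocytes, and none passed with an estimated correlation (macrophages adjusted p = 0.11, lymphocytes adjusted p = 0.51).

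Of the fast fibre genes 15 of 17 fell, such as Actn3, the alpha-actinin of fast fibres (4180 ± 615 against 9540 ± 543 CPM, −1.19 ± 0.12), and the troponin Tnnt3 (11700 ± 1360 against 23300 ± 1480, −0.993). Energy genes moved the same way, with falls in 19 of 21 glycolysis genes and a rise in 1 (Pygm, the muscle glycogen phosphorylase, −1.08 ± 0.11), in 32 of 35 oxidative phosphorylation genes (Cox6a2 −0.868 ± 0.078) and in 17 of 26 fatty acid oxidation genes (Acsl1 −0.852). The dystrophin complex list had 11 falls, such as Sgca (143 ± 13.1 against 240 ± 8.97 CPM, −0.749 ± 0.079) and Sgcb (−0.561), and 2 rises among 21. Of 12 Schwann cell genes 10 fell, of 16 circadian genes 10 fell and 1 rose (Hlf −2.01), and of 19 atrophy and proteolysis genes 8 fell and 1 rose (Capn3 −0.998, Ctsl 0.894). These 8 lists passed as lower in delEx44, with adjusted p = 1.4e-12 for fast fibre and adjusted p = 0.02 for atrophy genes, and none passed with an estimated correlation (adjusted p = 0.2 and adjusted p = 0.52). The neutrophil list had a median of −1.63 and a mean of −2.80, while its test pointed the other way (adjusted p = 0.91). The negative values came from WT replicate 3, at a level of 3.78 against −2.59 and −2.29 in the other WT libraries and −0.247, −0.356 and 0.191 in delEx44.

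In all, 7541 of 15013 genes passed, 3788 higher and 3753 lower, and 1482 and 362 of them by at least 1 log2 unit. No overlap between the 3 and 3 libraries was seen in 58.6% of all genes, where 10% is the share by chance. Camera called 17 of 30 lists and fry 22. With the correlation of each list estimated, camera called 0. Cell mixture and expression per cell are not separated in whole muscle.

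Corrected muscle at 4 weeks had less of the same inflammatory and young-fibre transcripts than delEx44 muscle. Spp1, the secreted matrix protein osteopontin, was at 5.32 ± 1.47 against 279 ± 29.2 CPM (log2 −5.70 ± 1.4, adjusted p = 0.0074), Mmp12 at 1.16 ± 0.385 against 35.5 ± 8.06 (−4.93 ± 0.36, adjusted p = 5.2e-06) and Myh3 at 8.54 ± 0.576 against 265 ± 149 (−4.96 ± 0.4, adjusted p = 1.2e-05; n = 3 each). Rgs1 (−5.16), Il1rn (−5) and the chitinase-like Chil3 (−4.86, adjusted p = 0.019) completed the largest falls. Higher were Ppp1r1a (32.4 ± 0.911 against 6.27 ± 1.78 CPM, 2.37 ± 0.18), Slc30a2 (2.71), Lamc3 (2.59), the carboxylesterase Ces1d (2.53), the spermine oxidase Smox (336 ± 99 against 67.8 ± 19.3, 2.31) and the imprinted Nnat (2.74 ± 1, adjusted p = 0.049). Nnat passed with the least margin of these and was lost in 9 of 14 other fits.

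Of the 27 macrophage genes 26 fell (Trem2 −3.57, Gpnmb −4.45; median −1.97), of 21 regenerating fibre genes 19 fell and 1 rose (Igf2 −1.92), and of 28 cell cycle genes 27 fell (Mcm6 −1.55). Falls were also found in 25 of 35 collagen and matrix genes (Postn −2.33 ± 0.28), 15 of 18 antigen presentation genes (H2-Aa −1.50), 16 of 24 chemokines beside 1 rise, and 11 of 28 interferon genes (Mx1 −1.65). All 17 fast fibre genes rose (Actn3 0.956 ± 0.12, Tnnt3 0.785), as did 34 of 35 oxidative phosphorylation genes (Cox6a2 0.768), 19 of 21 glycolysis genes and 17 of 26 fatty acid oxidation genes (Cpt2 0.738). In the dystrophin complex 9 genes rose (Sgca 0.690, Sgcb 0.518) and 2 fell, and 10 of 12 Schwann cell genes rose. A total of 6945 genes passed, 3313 higher and 3632 lower, and camera called 18 lists. None of these was called with the correlation estimated, where the macrophage and regenerating fibre lists each had adjusted p = 0.15 with an estimated correlation and fast fibre genes adjusted p = 0.34 with an estimated correlation.

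Between corrected and WT muscle at 4 weeks edgeR called 0 genes, while 1497 had an unadjusted p under 0.05. DESeq2 called 220 and limma-voom 0, and without corrected replicate 3 edgeR called 68. Macrophage genes stood higher as a list, with a median of 0.883 (adjusted p = 3.9e-43, and adjusted p = 0.078 with an estimated correlation), for example Lyz2 at 221 ± 31.8 against 120 ± 14.7 CPM (0.88 ± 0.17, adjusted p = 0.12). Interferon genes had a median of 0.924 (adjusted p = 0.087 with an estimated correlation; Ddx60 9.78 against 3.05 CPM, Oasl1 5.34 against 1.81) and antigen presentation genes 0.677 (adjusted p = 0.087 with an estimated correlation; H2-Ab1 37.6 against 21.1). Adjusted over the list alone, 24 of 27 macrophage, 26 of 28 interferon and 16 of 18 antigen presentation genes passed. Camera called 10 lists in all and fry 0, with fast fibre genes (−0.156), tendon and cartilage genes (−0.701), cell cycle genes (−0.196) and neutrophil genes (−4.56) lower. With an estimated correlation these 4 lists had adjusted p = 0.67, adjusted p = 0.37, adjusted p = 0.89 and adjusted p = 0.89. Tendon genes stood at 6.4 in WT replicate 3 against 5.2 and 5.07 in the other WT libraries, and cell cycle genes at 3.14 against 2 and 2.69. Ngp, a neutrophil granule gene, was at 57.3 CPM in WT replicate 3 (WT mean 19.1 ± 33.1), against a corrected mean of 0.249.

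**Figure D2:**
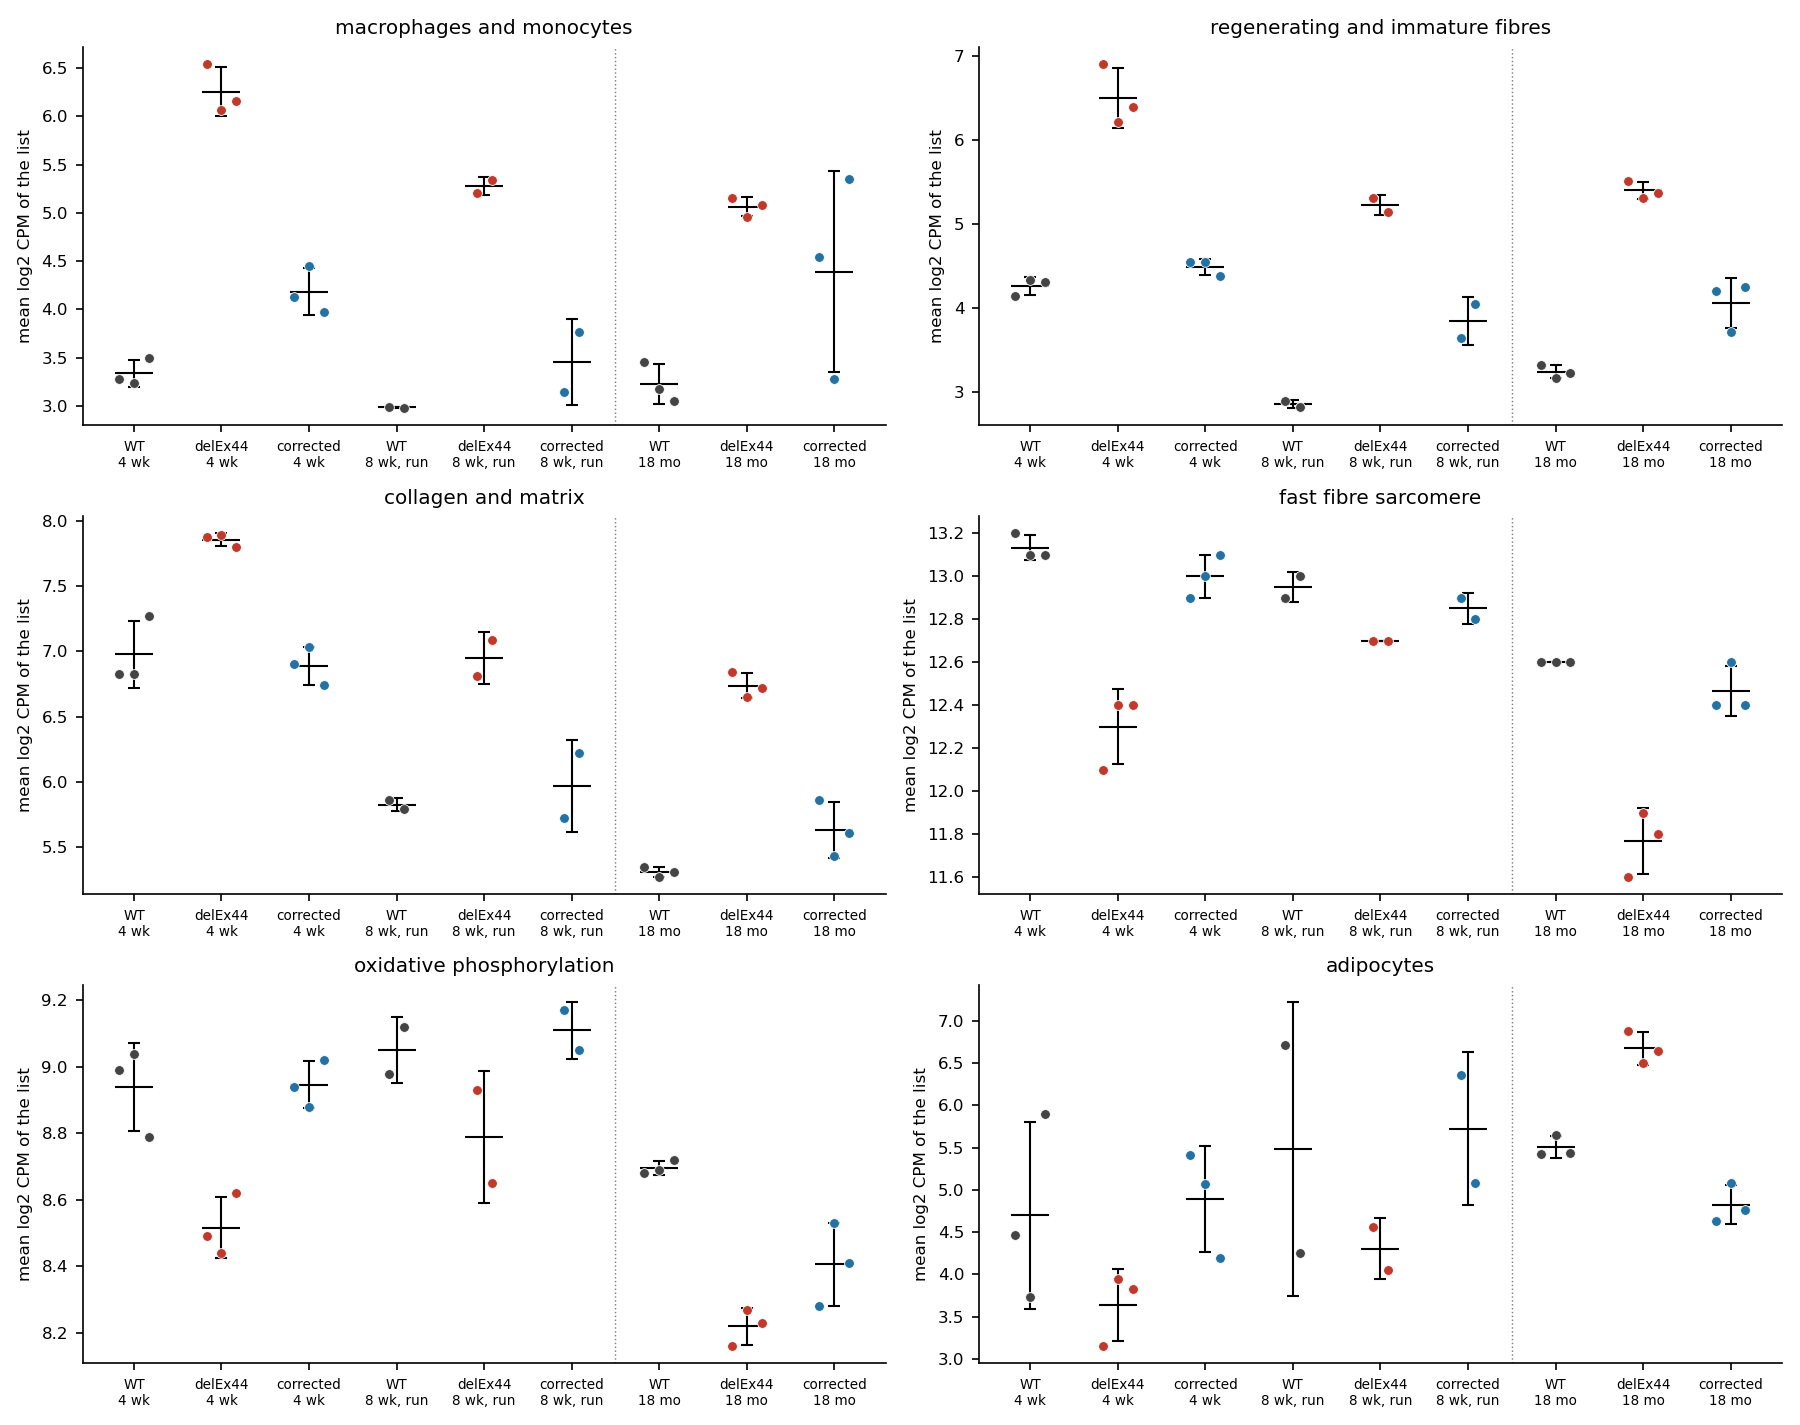
Level of 6 gene groups (mean log2 CPM) in every library, with the 2 tables separated by a dotted line. At 4 weeks the median log2 of macrophage genes was 2.88 for delEx44 against WT and −1.97 for corrected against delEx44.

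After running, delEx44 muscle again differed from WT mainly in macrophage, young-fibre and matrix genes. Mmp12 was at 58.4 ± 22.5 against 0.147 CPM (log2 8.62 ± 0.58, adjusted p = 1.1e-05), Rgs1 at 5.29 against 0.0141 (too few WT counts for a fold change), and Tmem8c, the fusion protein myomaker, at 11 against 0.161 (6.07, adjusted p = 3e-04; n = 2 each). Chrng was at 6.80 ± 2.49 against 0.102 CPM (6.02 ± 0.69), Il1rn at 5.52 against 0.16 (5.08) and the C-type lectin Clec4d at 5.35 against 0.172 (4.92). The phosphatase Dusp26 fell to 7.26 ± 0.796 from 73.1 ± 10.3 CPM (−3.33 ± 0.2, adjusted p = 4e-06), with Cdh4 (−3.43), Ces1d (−3.39), Ppp1r1a (−3.06) and Snph (−2.97). Lep, the fat hormone leptin, was at 3.13 against 23.9 ± 19.7 CPM (−2.93, adjusted p = 0.026) and was lost in 4 of 12 other fits, among them that without WT replicate 1 (−1.67, adjusted p = 0.19, in a range of 0.0078 to 0.19). That library had an adipocyte level of 6.71 against 4.25 in WT replicate 2, and Ucp1, a brown fat gene, at 23.4 against 0 CPM.

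Of 27 macrophage genes 26 rose (Trem2 4.16, Lyz2 2.19), as did 16 of 21 regenerating fibre genes (H19 1.9, Igf2 2.14) and 24 of 35 collagen and matrix genes (Col14a1 1.61, Lum 1.16). Of 20 neuromuscular junction and denervation genes 10 rose (Chrnb1 76.9 ± 1.13 against 38.8 ± 2.81 CPM, 0.989) and 1 fell. Chemokines had 12 rises in 24, antigen presentation 7 in 18 (H2-Aa 1.54), satellite cell genes 5 in 15, fibro-adipogenic progenitor genes 6 in 15 (Pdgfra 0.756) and interferon genes 4 in 28. Fatty acid oxidation had 17 falls in 26 (Acsl1 −1.08), oxidative phosphorylation 6 in 35 (Cox6a2 −0.628) and Schwann cell genes 6 in 12 beside 1 rise (S100b −1.46). Only 2 of 17 fast fibre genes fell (Mylk2 −0.796), and that list did not pass (median −0.188, adjusted p = 0.073). Here 4370 genes passed (2239 higher, 2131 lower), 2384 without WT replicate 2, and camera called 15 lists and fry 12. Macrophage, regenerating fibre and neuromuscular junction genes were the 3 lists still called with the correlation estimated, each at adjusted p = 0.044.

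Corrected muscle after running had lower macrophage and matrix transcripts than delEx44 muscle. Mmp12 was at 0.987 against 58.4 ± 22.5 CPM (log2 −5.86 ± 0.45, adjusted p = 4.8e-05), Gpnmb at 11.1 ± 3.48 against 182 ± 75.2 (−4.03), and Atp6v0d2, a proton pump subunit, at 0.793 against 17 (−4.40), with Rgs1 (−4.40), the integrin Itgax (−3.52) and Clec4d (−3.44; n = 2 each). Dusp26 was higher (49.6 ± 5.79 against 7.26 ± 0.796 CPM, 2.77 ± 0.2, adjusted p = 2.6e-05), as were Mettl21c (180 ± 15.4 against 28 ± 6.27, 2.68), Slc15a5 (4.46) and Lamc3 (2.83). The interferon-induced GTPases Tgtp1 (6.25 ± 5.41 against 0.812, 2.94) and Gbp4 (62.5 ± 48.1 against 9.61, 2.7) also rose, with a wide spread between the 2 corrected libraries. Falls were found in 25 of 27 macrophage genes (Trem2 −2.85), 26 of 35 collagen and matrix genes (Col14a1 −1.59), 16 of 21 regenerating fibre genes (Igf2 −1.91, Myh3 −2.66) and 10 of 20 junction genes (Chrnb1 −0.557). Oxidative phosphorylation had 13 rises in 35 (Cox5a 0.490) and fatty acid oxidation 11 in 26 (Acsl1 1.14). A total of 3485 genes passed (1618 higher, 1867 lower), and this number was 1197 without corrected replicate 1 and 1877 without delEx44 replicate 2. Camera called 13 lists and fry 7, and camera with estimated correlations 0, where macrophage genes had adjusted p = 0.14 with an estimated correlation.

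Against WT after running, 3 genes passed in corrected muscle, with 1455 at an unadjusted p under 0.05. Dmd was lower (92.1 ± 4.76 against 154 ± 8.29 CPM) and so was Nbea, a vesicle traffic scaffold (7.15 ± 0.516 against 13.3 ± 0.323, −0.895 ± 0.13, adjusted p = 0.036; n = 2 each). The third gene, the predicted Gm15446, was named after its values were seen, and was listed at 0 in WT and at 1.10 CPM in corrected muscle. DESeq2 called 82 genes and a fit of only these groups 0 (1089 unadjusted), and the count was 0 without WT replicate 1 (1544 unadjusted), 7 without WT replicate 2, 25 without corrected replicate 1 and 1 without corrected replicate 3. Interferon genes (median 0.833, adjusted p = 4.9e-24, and adjusted p = 0.18 with an estimated correlation) and regenerating fibre genes (0.775, adjusted p = 8.9e-16, and adjusted p = 0.1 with an estimated correlation) stood higher as lists, for example Xaf1 at 8.05 against 4.33 CPM and H19 at 926 against 474. Adjusted over the list alone, 17 of 28 and 8 of 21 of their members passed. Camera called 10 lists and fry 0.

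Matrix and cell cycle transcripts were lower in run 8-week than in sedentary 4-week muscle in all 3 genotypes. Col3a1, the type III collagen chain, was at 873 ± 121 after running against 3400 ± 82.2 CPM at 4 weeks in WT (log2 −1.96), 2110 ± 428 against 5450 ± 298 in delEx44 (−1.37) and 1130 ± 236 against 3880 ± 545 in corrected muscle (−1.78). H19, an imprinted growth-related RNA, fell by 2.99 log2 units in WT, 1.85 in delEx44 and 2.00 in corrected muscle. Among the smallest p-values in WT were those of Nqo1, a quinone reductase (32.6 ± 2.44 against 10.3 ± 0.246 CPM, 1.66 ± 0.091, adjusted p = 1.3e-06), Cbx7 (1.23 ± 0.096), the ubiquitin ligase subunit Asb2 (1050 ± 135 against 417 ± 22.4, 1.33), C1qtnf6 (−1.78) and the lysyl oxidase Loxl2 (39.9 ± 0.885 against 114 ± 2.61, −1.52 ± 0.1). In delEx44 they included Ctxn3 (109 ± 22.3 against 13.5 ± 0.699 CPM, 3.01 ± 0.19, adjusted p = 7.9e-06), and in corrected muscle Exosc5 (1.09, adjusted p = 3.9e-05), Nqo1 (1.07) and the metalloproteinase Adamts12 (−1.50). Dmd fell in WT (−0.49 ± 0.089, adjusted p = 0.0016) and corrected muscle (−0.80 ± 0.091, adjusted p = 0.00015) and did not pass in delEx44 (0.05 ± 0.09, adjusted p = 0.67).

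Of 35 collagen and matrix genes 26 fell in WT, 25 in delEx44 beside 1 rise, and 27 in corrected muscle (medians −1.26, −0.958 and −1.14). Cell cycle genes had 15, 26 and 12 falls (Kif20a −2.02, −1.85 and −1.50), and regenerating fibre genes 12, 18 and 7. Tnmd, the tendon gene tenomodulin, fell by 2.37, 1.69 and 1.95 log2 units, with 4 of 11 tendon and cartilage genes lower in each genotype. Interferon genes fell in 5, 26 and 11 of 28 cases (Rtp4 −1.57 in delEx44), and in 0, 27 and 14 when adjusted over the list alone. Macrophage genes fell in 2, 23 and 11 of 27 (Mrc1 −1.13, −0.893 and −1.56). Fast fibre genes had 5 falls and 1 rise in WT (Mylpf 14100 ± 660 against 27400 ± 491 CPM) and 9 rises in delEx44 (Atp2a1, the fast calcium pump, 27800 against 14900, 0.896). Circadian genes had 5 rises and 0 falls in WT, where camera did not call the list (adjusted p = 0.073). They had 10 rises and 3 falls in delEx44 (Cry2 1.40) and 7 and 2 in corrected muscle (Cry2 0.756).

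The genes passing were 4138 in WT, 5355 in delEx44 and 3878 in corrected muscle, with 879 higher and 963 lower in all 3. In WT the count was 2488 without run replicate 1 and 2216 without run replicate 2, in delEx44 3111 without run replicate 1 and in corrected muscle 1324 without run replicate 1. Camera called 11, 15 and 12 lists, fry 8, 12 and 7, and camera with estimated correlations 0, where collagen genes had adjusted p = 0.16, adjusted p = 0.39 and adjusted p = 0.34. Neutrophil genes were higher after running in delEx44 (5 rises, adjusted p = 0.043) and corrected muscle (2 rises, adjusted p = 0.003), and with an estimated correlation these were adjusted p = 0.75 and adjusted p = 0.79. The 2 corrected rises, Camp and Ltf, were lost in 5 and 7 of 12 other fits, including that with the bone and marrow covariate. In delEx44 each of these 2 was lost in 4 of 12. Ibsp, a bone gene, was at 3.29 to 14.8 CPM in the run libraries, 54.6 in sedentary WT replicate 3 and at most 1.68 in the other 8. The neutrophil list level was 2.16 to 3.69 in the 6 run libraries, 3.78 in sedentary WT replicate 3 and at most 0.191 in the other 8 sedentary libraries at 4 weeks. In those delEx44 mice Ltf was at 12.5 ± 9.01 against 0.0684 CPM and Camp at 10.7 ± 8.92 against 0.0309.

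**Figure D3:**
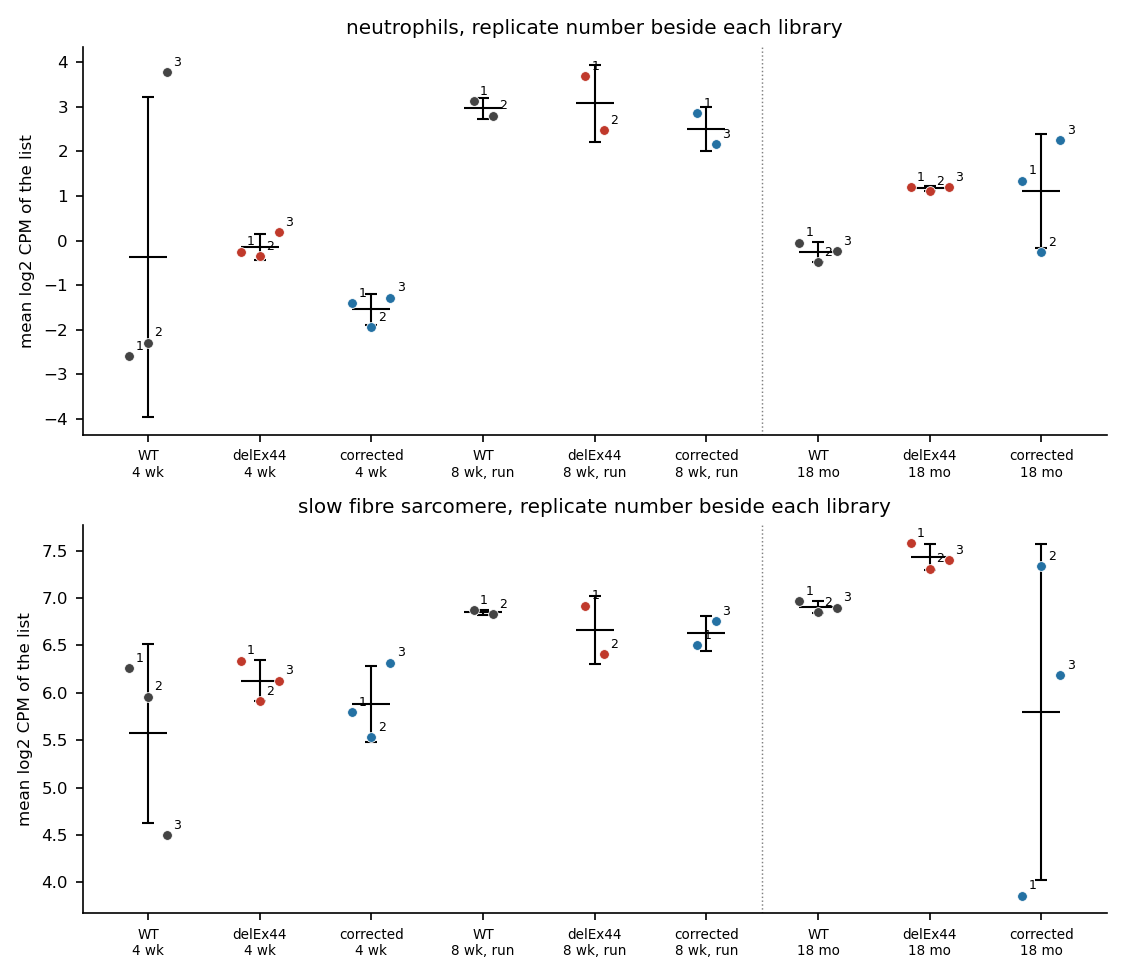
Levels of neutrophil and slow fibre genes (mean log2 CPM) in every library, with replicate numbers. Sedentary WT replicate 3 at 4 weeks had a neutrophil level of 3.78, and corrected replicate 1 at 18 months a slow fibre level of 3.86.

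Whether the step to the run group differed between genotypes was tested as an interaction. For delEx44 against WT 132 genes passed (88 higher, 44 lower), led by Dhrs7c (log2 0.857 ± 0.1), Ctxn3 (2.42 ± 0.27) and Rnf123 (0.756 ± 0.092), each at adjusted p = 0.006. Actn3 (1.00 ± 0.19, adjusted p = 0.032) and Myom2 (0.893) were among 5 of 17 fast fibre genes that passed, all higher, with a list median of 0.672 (adjusted p = 7.5e-19, and adjusted p = 0.32 with an estimated correlation). The clock genes Dbp (4.66, adjusted p = 0.041) and Arntl (−2.68 ± 0.44, adjusted p = 0.028) passed as well, and Dmd did not (0.55 ± 0.13, adjusted p = 0.06). For corrected against delEx44 213 genes passed (61 higher, 152 lower), among them Dmd (−0.86 ± 0.13, adjusted p = 0.018), Sgca (−0.619, adjusted p = 0.036), Atp2a1 (−0.939, adjusted p = 0.03) and Rnf123. Both counts moved with single libraries. The former was 43 and 25 without sedentary WT replicates 1 and 2, 24 without sedentary delEx44 replicate 1, 11 and 61 without WT run replicates 1 and 2, and 25 and 84 without delEx44 run replicates 1 and 2. The latter was 14 and 111 without sedentary delEx44 replicates 1 and 3, 35, 31 and 19 without sedentary corrected replicates 1 to 3, 68 and 49 without delEx44 run replicates 1 and 2, and 34 and 0 without corrected run replicates 1 and 3.

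At 18 months delEx44 muscle had less fast fibre transcript than WT and more transcript of matrix, of junction and denervation genes, and of fat cells. The fast fibre difference was there at 4 weeks too, and camera did not call that list in the age interaction (median log2 0.0307, adjusted p = 0.81). Cdkn2a, which encodes the cell cycle inhibitors p16 and p19, was at 9.31 ± 0.62 against 0.0594 ± 0.0738 CPM (log2 7.39 ± 1.1, adjusted p = 0.00083), and Sln, the calcium pump inhibitor sarcolipin, at 167 ± 12.2 against 3.68 ± 0.22 (5.51 ± 0.22, adjusted p = 2.2e-06; n = 3 each). The hyaluronan synthase Has1 was at 15.4 ± 10.9 against 0.285 CPM (5.76 ± 0.77), Chrng at 5.96 ± 0.756 against 0.192 ± 0.0603 (4.94 ± 0.35), Tmem8c at 7.77 against 0.247 (4.92) and the chemokine Ccl7 at 21.9 ± 5.7 against 0.785 (4.77 ± 0.95). The growth factor carrier Fgfbp1 fell to 0.297 from 9.98 ± 1.69 CPM (−5.05 ± 0.3, adjusted p = 3.2e-06) and Asb4 to 2.06 ± 0.225 from 37 ± 4.93 (−4.16 ± 0.28), with Slc15a5 (−4.31), Exph5 (−4.28), the oxytocin receptor Oxtr (−4.21, adjusted p = 0.021) and Tph2 (−4.20, adjusted p = 0.013). Oxtr was lost in 3 of 16 other fits and Tph2 in 1.

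Of 20 regenerating fibre genes 17 rose (Myh8 62 ± 6.85 against 9.83 ± 0.477 CPM, 2.66 ± 0.12; Tnnt2 2.97), as did 32 of 35 collagen and matrix genes (Ctgf 253 ± 24.8 against 56.5 ± 8.03, 2.16 ± 0.14; Timp1 4.15 ± 0.31) and 12 of 15 fibro-adipogenic progenitor genes (Cxcl14 1.26). Adipocyte genes had 11 rises and 1 fall in 15 (Retn, or resistin, 38.7 ± 6.2 against 10.2 ± 0.947, 1.92 ± 0.14; Pparg 1.40), and junction genes 13 rises and 1 fall in 20 (Chrnd 2.81 ± 0.12). Macrophage genes rose in 24 of 27 cases (Lgals3 65.3 ± 3.8 against 14.6 ± 2.04, 2.17), chemokines in 16 of 22 and lymphocyte genes in 12 of 16 (Cd2 1.97). All 35 oxidative phosphorylation genes fell (Sdha 795 ± 48 against 1230 ± 28.5 CPM, −0.635), with 19 of 21 glycolysis genes beside 2 rises (Pygm −1.37), 18 fatty acid oxidation genes (Acadvl −0.882) and 12 of 17 fast fibre genes (Myh4, the fastest myosin, 15500 ± 2960 against 53100 ± 4180, −1.78 ± 0.14). Passing genes numbered 7549 (4131 higher, 3418 lower), and 66.2% of all genes had no overlap, against 10% by chance. Camera called 18 lists and fry 24, and with an estimated correlation none passed (collagen and regenerating fibre genes adjusted p = 0.18 each, adipocytes adjusted p = 0.34).

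Corrected muscle at 18 months had more fast fibre and less fat cell and matrix transcript than delEx44 muscle. Myh4 was at 51000 ± 2650 against 15500 ± 2960 CPM (log2 1.72, adjusted p = 2.8e-05), Sln at 5.5 ± 1.8 against 167 ± 12.2 (−4.92 ± 0.21, adjusted p = 5.1e-06) and Cfd, the fat cell protease adipsin, at 30.8 ± 13.7 against 467 ± 50.9 (−3.92; n = 3 each). Has1 (−5.77), the early growth response gene Egr3 (1.06 against 44 ± 12.9, −5.34), the keratin Krt18 (2.50 against 46.1 ± 10.9, −4.20) and the carboxylesterase Ces1f (−3.91) fell too. Among the largest rises were Odf3l2 (4.01), Asb4 (3.31), Tmem132b (38.2 ± 5.92 against 4.34 CPM, 3.14 ± 0.22), Doc2b (3.02) and the glycogen regulator Ppp1r3c (1710 ± 797 against 227 ± 43.7, 2.91).

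Falls were found in 13 of 15 adipocyte genes beside 1 rise (Pparg −1.91, Retn −2.65), 31 of 35 collagen and matrix genes (Ctgf −1.98), 17 of 20 regenerating fibre genes (Myh8 −1.78), 11 junction genes beside 2 rises, and 11 of 15 progenitor genes. Fast fibre genes had 14 rises and 1 fall, glycolysis genes 19 and 1, and oxidative phosphorylation 13 rises. Macrophage genes did not pass as a list (median −0.473, adjusted p = 0.23), with 1 rise (Cd163 74.1 ± 25.1 against 40.8 ± 1.35 CPM, 0.861, adjusted p = 0.0097) and 0 falls in 27, and neither did interferon (0.304, adjusted p = 0.66) or antigen presentation genes (−0.442, adjusted p = 0.26). A total of 5880 genes passed (2817 higher, 3063 lower). Camera called 14 lists and fry 15, and camera with estimated correlations 0, where collagen and adipocyte genes had adjusted p = 0.15 each with an estimated correlation.

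Against WT at 18 months corrected muscle differed in some fetal muscle and respiratory chain genes. Interferon and macrophage genes lay above WT by their list medians, with a wide spread between the corrected libraries. Few members of the inflammatory lists passed over all genes. Actc1, the cardiac actin of immature fibres, was at 160 ± 55.4 against 36.5 ± 1.15 CPM (log2 2.13 ± 0.23, adjusted p = 0.0098), the metallothioneins Mt2 at 100 ± 71.5 against 8.59 ± 0.291 (3.54 ± 0.54, adjusted p = 0.024) and Mt1 at 57.9 ± 41.5 against 8.89 (2.7), and the myeloid Ms4a6c (2.43), Ms4a6d (2.40) and Gpr65 (2.3) were higher. The adipocyte genes Adig (−1.79, adjusted p = 0.024) and Plin1 (9.88 against 25.6, −1.37, adjusted p = 0.022) were lower, with Exph5 (−1.97), Frzb (−1.56), Tshr (−1.49), Ces1d (−1.41) and Tenm4 (−1.40). Of 20 regenerating fibre genes 9 rose (Myl4 1.71, Myh8 0.882) and of 20 junction genes 5 (Chrng 2.69). Of 35 oxidative phosphorylation genes 11 fell (Ndufb8 298 against 373 CPM, −0.322) and 32 when adjusted over the list alone. Interferon genes had 2 rises (24 over the list alone; Oasl1 2.32, median 1.61), macrophage genes 0 (17 alone; median 1.42) and chemokines 4 (Ccl6 1.85). With an estimated correlation these 3 lists had adjusted p = 0.4, adjusted p = 0.4 and adjusted p = 0.33.

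In this comparison 683 genes passed (335 higher, 348 lower), and 578 of them also passed between delEx44 and WT, 534 in the same direction. Of all 14337 genes, 7549 passed between delEx44 and WT. Both comparisons share the WT libraries, which raises the overlap and the agreement in direction, and neither was simulated. The count was 9 without WT replicate 2, 49 without WT replicate 1, 138 without WT replicate 3, 128 without corrected replicate 1, 2859 without corrected replicate 2 and 441 without corrected replicate 3. Of the genes named above, Mt1, Ms4a6c and Gpr65 were each lost in 9 of 16 other fits, Ms4a6d in 10, Mt2 in 5 and Actc1 in 3. Camera called 15 lists and fry 5, and camera with estimated correlations 0, where regenerating fibre genes had adjusted p = 0.32 and oxidative phosphorylation adjusted p = 0.33 with an estimated correlation. Macrophage levels in corrected replicates 1 to 3 were 4.54, 3.28 and 5.35, against 3.05 to 3.46 in WT, a range that holds replicate 2, and 4.96 to 5.15 in delEx44. Slow fibre levels in these 3 libraries were 3.86, 7.34 and 6.19, with Myh7, the slow myosin, at 0.811, 406 and 60.1 CPM.

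Whether genes changed back in direction in the corrected groups was set against a simulation, because both comparisons share the delEx44 libraries. The simulation held no genotype effect, so it does not stand for mutant muscle without correction. A share of opposite signs does not show how far a gene moved. At 4 weeks 99.5% of the genes called in delEx44 against WT had the opposite sign in corrected against delEx44 (simulated 74.9%), after running 98.9% (80.4%) and at 18 months 96.4% (74.6%). Genes such as Mmp12 and Myh3, called higher and then lower, numbered 3131 at 4 weeks, 1562 after running and 2558 at 18 months. Genes such as Ppp1r1a, lower and then higher, numbered 2943, 1245 and 2391. These counts were not simulated, and the shared libraries raise them. Without corrected replicate 2 the 18-month share was 90.1%.

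A test without shared libraries took the 200 genes with the smallest p in each direction in one table to the mice of the other. Genes higher in delEx44 at 18 months were lower in corrected than in delEx44 muscle at 4 weeks (175 of 200, median log2 −0.509, p = 0.018 with an estimated correlation) and after running (171 of 200, −0.546, p = 0.0074 with an estimated correlation). Genes lower in delEx44 at 18 months were higher in corrected than in delEx44 muscle at 4 weeks (196 of 200, 0.648, p = 0.0086 with an estimated correlation) and after running (185 of 200, 0.359, p = 0.034 with an estimated correlation). Against WT the corrected muscle had medians of −0.0141 and −0.0804 at 4 weeks and 0.0749 and −0.143 after running for these 2 sets, none of which passed with an estimated correlation. Genes higher in delEx44 at 4 weeks had a median of 0.826 above WT in corrected muscle at 18 months (193 of 199 higher). The set did not pass with an estimated correlation (p = 0.14). WT libraries spanned −0.14 to 0.198 for these genes, a range that holds corrected replicate 2. The genes lay 0.928, 0.053 and 1.34 above WT in replicates 1 to 3, against 1.49, 1.40 and 1.41 in delEx44. Their fall from delEx44 had a median of −0.565 (182 lower; p = 0.45 with an estimated correlation), while genes lower in delEx44 at 4 weeks were higher in 193 of 200 cases (0.59, p = 0.026 with an estimated correlation).

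**Figure D4:**
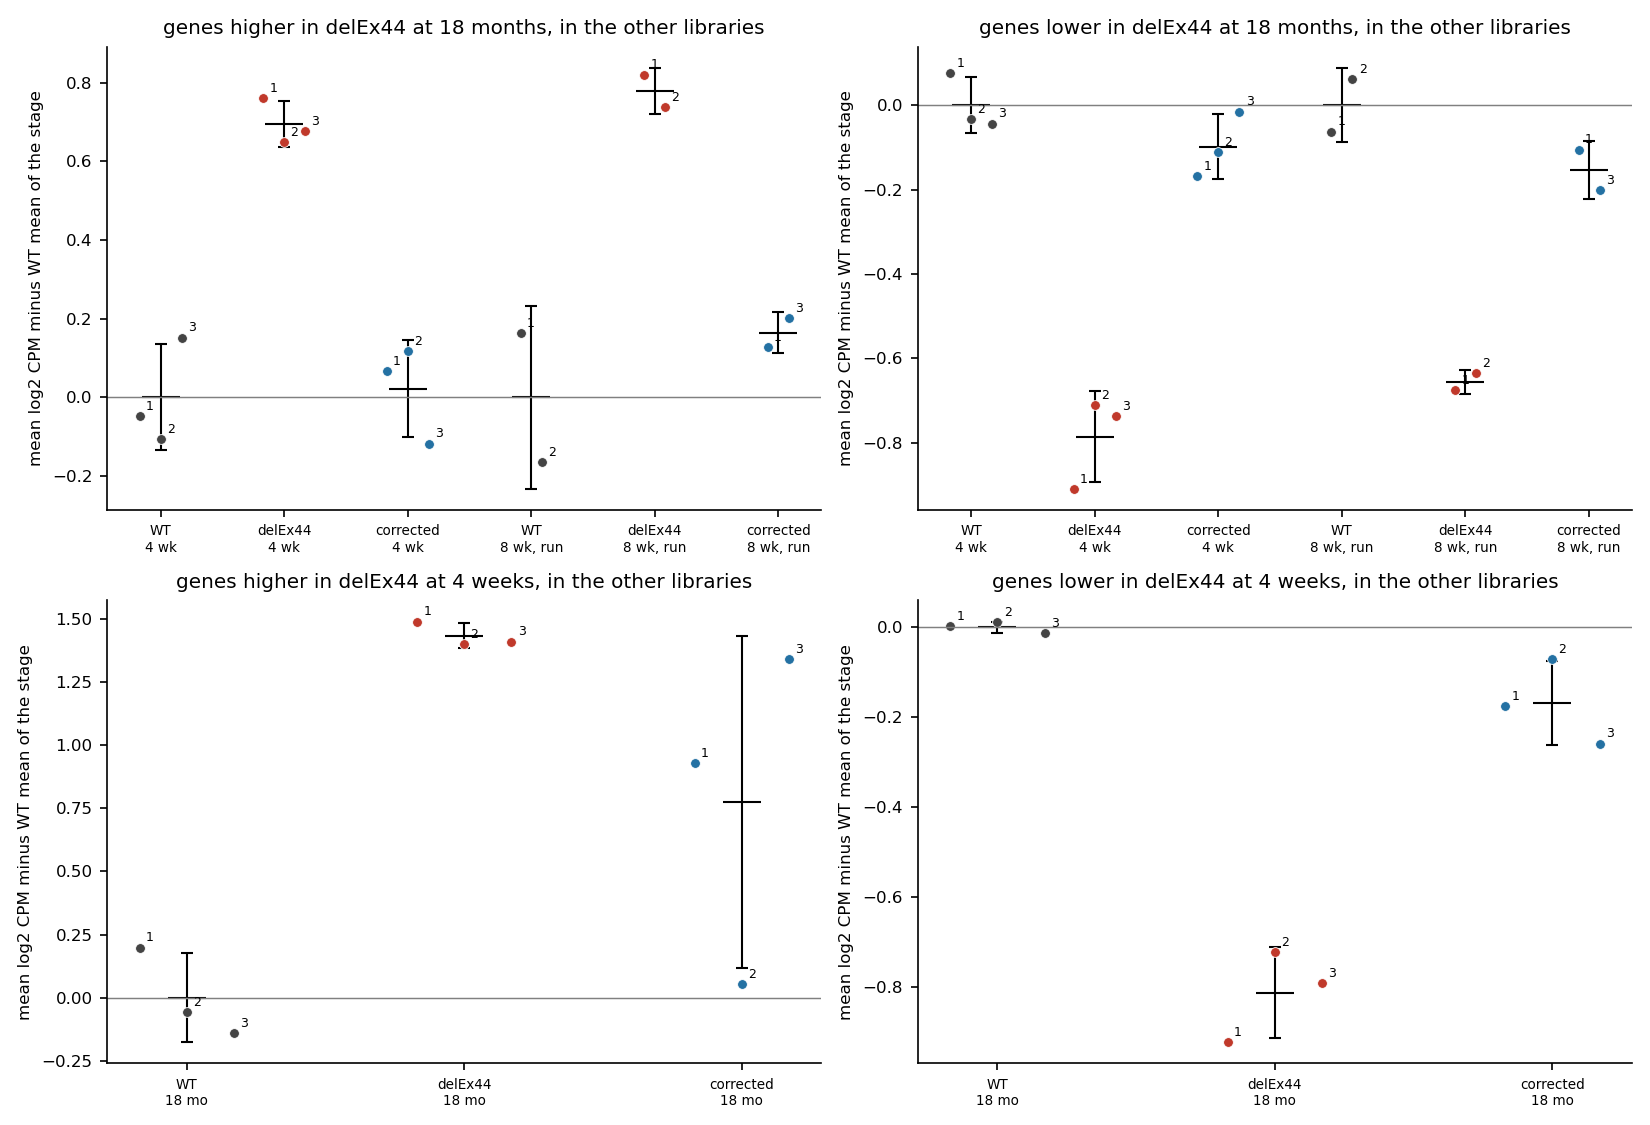
Genes chosen in one table, shown in the mice of the other as mean log2 CPM minus the WT mean, with replicate numbers. Genes higher in delEx44 at 4 weeks were 0.928, 0.053 and 1.34 above WT in the 18-month corrected replicates 1 to 3.

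Genotype differences were compared between sedentary mice of 4 weeks and 18 months as interactions. For delEx44 against WT 1632 genes passed (1048 higher, 584 lower), with Actc1 (log2 4.20, adjusted p = 1.9e-06), the glutamate transporter Slc1a3 (4.36) and the prostaglandin dehydrogenase Hpgd (2.08) higher, and Tpx2 (−3.29), the kinase Aurka (−2.17) and Asb4 (−3.26) lower. Adipocyte genes passed in 11 of 16 cases, all higher (Pparg 1.35 ± 0.18, adjusted p = 2e-04; median 2.12, list adjusted p = 4.8e-10, and adjusted p = 0.39 with an estimated correlation). Macrophage genes passed in 5 cases, all lower (Gpnmb −2.59, Lgals3 −2.43; median −1.10, adjusted p = 0.75 with an estimated correlation). For corrected against delEx44 2370 genes passed (1157 higher, 1213 lower), with 12 adipocyte genes lower (Pparg −1.75 ± 0.18, adjusted p = 4.7e-05; median −3.23, adjusted p = 1.7e-14, and adjusted p = 0.27 with an estimated correlation), 13 cell cycle genes higher (Aurka 1.85) and 12 macrophage genes higher (Lgals3 3.44 ± 0.48, Gpnmb 3.26). The cell cycle list had adjusted p = 0.41 and the macrophage list adjusted p = 0.56 with an estimated correlation. Adipocyte levels at 4 weeks were uneven, at 4.46, 3.73 and 5.9 in WT, 3.15, 3.94 and 3.83 in delEx44 and 5.41, 5.07 and 4.19 in corrected muscle. Ucp1 was there at 39.2, 14.3 and 0.726 CPM against 1.09 at most in delEx44. Part of these adipocyte differences thus lay in 4-week libraries. Utrn passed for delEx44 against WT (0.37 ± 0.1, adjusted p = 0.025) and Dmd in neither (0.32 ± 0.2, adjusted p = 0.34, and −0.53 ± 0.2, adjusted p = 0.077). The corrected mice of the 2 ages differed in vector dose and type as well as in age. Age also came with the count table in every genotype. Records that name no gene held 27.4% to 34.2% per library in the first table and 42.2% to 48.3% at 18 months. A genotype difference that varied with the table thus cannot be told apart from one that varied with age. Across 14139 genes 1550 were higher and 1241 lower in delEx44 than in WT at all 3 stages, Dmd among the latter.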

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

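The tests of neutrophils brought in by running, of mixed muscle and of fewer slow fibres in this part, the fits without 2 WT libraries, and the choice of lists by 2 tests were made after the results were seen. The first 4 results were taken up because a genotype difference itself differed between groups of mice, by an interaction test, and the last 2 patterns because single libraries stood apart from their group. No list of the 4 interactions passed with an estimated correlation. Vector dose and type differed only for the 18-month corrected mice. The 18-month libraries of every genotype came in a count table of their own, so age and table cannot be told apart in the age interactions.

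Muscle of delEx44 and WT mice differed in 132 genes in the step from sedentary 4-week to run 8-week mice. Higher in delEx44 were Dhrs7c (log2 0.857), a reductase of the sarcoplasmic reticulum, Ctxn3 (2.42), Rnf123 (0.756), Cpe (0.716), the myosin-binding Mybph (1.64) and Kcne1l (2.19). Lower were Dapp1 (−1.68), Otub2 (−1.62), Asb2 (−1.17), Rnpep (−0.749), Slc16a9 (−1.61) and Tbc1d1 (−1.25). As lists, dystrophin complex genes (0.30) and fast fibre genes (0.672) rose more, or fell less, in delEx44, at adjusted p = 0.33 and adjusted p = 0.32 with an estimated correlation. The count was 5 without 4-week WT replicate 3 and WT run replicate 1, 11 and 61 without WT run replicates 1 and 2, 43, 25 and 167 without 4-week WT replicates 1 to 3, 24 without 4-week delEx44 replicate 1, and 25 and 84 without delEx44 run replicates 1 and 2.

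Corrected and delEx44 muscle differed in 213 genes in the same step. Higher in corrected muscle were Vcpkmt (1.68), Adss (0.625), Thpo (1.59), the galectin Lgals1 (0.885), Gmnn (1.22) and Dtymk (0.76), and lower were Cpe (−0.745), Acadsb (−0.666), the Z-disc gene Myoz3 (−0.864), Sptb (−0.981), Rnf123 (−0.662) and Dmd (−0.858). Dystrophin complex genes (−0.344) and fast fibre genes (−0.506) were lower as lists, each at adjusted p = 0.38 with an estimated correlation. With edgeR the count was 34 and 0 without corrected run replicates 1 and 3 (for the latter 2243 at an unadjusted p under 0.05), 68 and 49 without delEx44 run replicates 1 and 2, 35, 31 and 19 without 4-week corrected replicates 1 to 3, and 14 and 111 without 4-week delEx44 replicates 1 and 3. DESeq2 with all libraries called 864.

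Between 4 weeks and 18 months the difference of delEx44 from WT changed in 1632 genes. It rose for Actc1 (4.20), Slc1a3 (4.36), Lrrn4cl (2.00), Hpgd (2.08), Cxcl14 (1.39) and Rap1gap2 (1.69), and fell for the sodium-calcium exchanger Slc8a1 (−1.36), Tpx2 (−3.29), Mib1 (−1.49), Aurka (−2.17), Asb4 (−3.26) and Asb2 (−1.69). Lists that rose were adipocytes (2.12), collagen and matrix (0.464), fibro-adipogenic progenitors (0.425), immediate early genes (0.786), neuromuscular junction (0.396) and Schwann cells (0.542). With an estimated correlation their adjusted p-values were 0.39, 0.39, 0.56, 0.39, 0.52 and 0.39, and only 4 of 20 junction and 3 of 15 progenitor genes passed as higher. The real grouping of these 12 libraries fitted alone gave 2005 genes. Among 50 groupings, 3 gave as many, the real one among them, with 9747 in the highest other. The 2 others kept or exchanged the genotypes of a whole age, so they held a genotype difference by construction. This count therefore cannot decide on chance.

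The difference of corrected from delEx44 muscle changed between the ages in 2370 genes. It rose for Tmpo (1.44), Rai14 (1.01), Peg10 (1.98), Aurka (1.85), Sept9 (1.17) and Grb10 (0.995), and fell for Hpgd (−2.46), Lrrn4cl (−2.14), Bche (−1.72), Crhr2 (−2.27), Slc25a23 (−1.35) and Abcd2 (−1). Cell cycle (1.3) and satellite cell genes (0.29) rose as lists, and adipocytes (−3.23), circadian (−0.304), progenitor (−0.577), immediate early (−0.928) and Schwann cell genes (−0.882) fell. With an estimated correlation cell cycle genes had adjusted p = 0.41 and the other 6 lists adjusted p = 0.27. The real grouping gave 2231 genes and 4 of 50 groupings gave as many, with 8522 in the highest other. Of the other groupings, 9 in each interaction kept or exchanged the genotypes of one age whole, a feature looked for after their values were seen, and 2 of the 9 for delEx44 against WT and 3 of the 9 here gave as many. The remaining ones of the 9 gave fewer than the real grouping, and the groupings without this feature 0 at most. A grouping that exchanges the genotypes of a whole age adds the 2 genotype differences in place of subtracting them. High counts there were thus set by the design, and these counts cannot decide on chance in either interaction.

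Bone and marrow transcripts were present in the 6 run libraries and in sedentary 4-week WT replicate 3, where Ibsp was at 54.6 and Ngp at 57.3 CPM. That library was sedentary by its label. In the run libraries the lowest neutrophil level lay 1.97 log2 units above the highest of the other 8 sedentary ones. Neutrophils brought in by running, marrow tissue and age could each give this, so they cannot be told apart for the neutrophil genes. The bone gene Ibsp had 119 to 498 counts in the run libraries and at most 79 in those 8. The red cell gene Slc4a1 had 157 to 786 against at most 14. This argues against neutrophils alone as the source of these 2 genes. Bone and marrow tissue collected with the muscle may be a source. Of 25 markers whose values had not been looked at, 64% were higher in both that library and the run mean than in the other 8 (4 of 10 for bone, 12 of 15 for marrow), between the bounds of 75% and 50% set for and against it, so tissue pickup and other sources cannot be told apart.

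At 18 months corrected replicates 1 and 3 had more immune transcripts than replicate 2, with 218 genes at least 2-fold higher in both. For lymph node tissue, 0% of 10 B cell and lymph node markers were higher in both than in the other 7 libraries, but lymphocyte levels were 0.167 to 0.658 in delEx44 against −0.49 and −0.256 here, which would hide a small share, so the bound set against it was too strict and this source cannot be told apart. A mixture of corrected and uncorrected muscle was tested by the interferon level of replicate 3. It lay 0.99 log2 units above the highest delEx44 library, whose group spanned 0.35. This argues against a mixture as the whole cause in replicate 3. It does not exclude one, since 3 delEx44 mice may not span all uncorrected muscle. Of the 218 genes 52.3% exceeded that highest library in replicate 3 (13.8% in both replicates), but they were chosen for being high there. For replicate 1 such a mixture may be a cause, with 19.3% of the 218 genes above the highest delEx44 library, although its neutrophil level was 1.34 against 1.11 to 1.2 in delEx44. A part of the muscle with fewer slow fibres cannot be told apart either, since its value (−0.66, the higher of the 2 slow fibre levels minus the lowest of the WT and delEx44 libraries) restates what was seen first, and replicate 1 had the lower slow fibre level (3.86 against 6.19) but also the lower interferon level (3.33 against 4.75). Age and labelled doses were the same in these 3 mice, and no biological explanation given by the design was tested.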

How the results depend on the processing

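The covariate fits, the fits without 2 WT libraries and those without Rn45s in this part were chosen after the data were seen. Of 969 named results that passed, 712 passed in every alternative, 257 were lost in at least one and 0 reversed. Over all summary values, 380 alternatives stayed the same, 84 moved and 10 no longer passed.

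Genes called between corrected and WT at 4 weeks were 220 with DESeq2 and 1 with the bone and marrow covariate. For corrected against WT after running they were 82 with DESeq2 and 0 with only the groups compared, and at 18 months 1638 with DESeq2, 445 with limma-voom, 16 with only the groups compared, 252 with the replicate block and 204 with the slow fibre covariate. Replicate numbers at 18 months did not pair the libraries (correlations −0.138 to 0.0867). With only the groups compared, which leaves fewer libraries to estimate the spread, delEx44 against WT after running gave 2330, corrected against delEx44 1256 and the running interaction of delEx44 and WT 41. DESeq2 gave 718 for that interaction and 864 for that of corrected and delEx44. Without the 2 WT libraries that stand apart, WT running gave 2145 genes and that interaction 5, and with the marrow covariate corrected running gave 2436. The cause of these differences was not tested.

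Leaving out 1 library gave, at 4 weeks, 5977 to 7272 genes for delEx44 against WT, 5321 to 6426 for corrected against delEx44 and 0 to 68 for corrected against WT. After running the ranges were 2384 to 3187, 1197 to 2886 and 0 to 25, and at 18 months 5949 to 6887, 4152 to 6256 and 9 to 2859. Running gave 2216 to 3676 in WT, 3111 to 4869 in delEx44 and 1324 to 3590 in corrected muscle. The running interactions gave 11 to 167 and 0 to 308, and the age interactions 1118 to 1426 and 1598 to 2984. Ends past 1.5 times came without 4-week corrected replicate 3 (68), WT run replicate 2 (2384 and 2216), corrected run replicate 1 (1197, 25 and 1324), WT run replicate 1 (0 and 11), delEx44 run replicate 1 (3111), corrected run replicate 3 (0), and at 18 months WT replicate 2 (9) and corrected replicate 2 (2859). The lists called in WT running were 12 to 17. Opposite signs were found in 98.7% to 99.8% of genes at 4 weeks, 98% to 99.7% after running and 90.1% to 97.8% at 18 months. Where 1 run library was left, it was assumed to vary like the other groups.

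With an estimated correlation, lists called were 3 for delEx44 against WT after running and 0 in every other comparison. Fry called 0, 0 and 5 lists for corrected against WT at the 3 stages, 7 for corrected against delEx44 after running, 7 for corrected running, 2 and 2 for the running interactions and 7 for the age interaction of corrected and delEx44. Medians of genes taken from the other table that no longer passed with an estimated correlation were −0.0804, 0.0749 and −0.143 for corrected against WT at 4 weeks and after running, and −0.565, 0.826 and −0.127 at 18 months. By construction an estimated correlation widens the test. At 30.6 to 38.1 and 23.1 to 31.3 M counts per library, simulated 1.5-fold changes were missed more often than larger ones.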

Other observations

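The tests of the sex-linked genes in this part were chosen after the values were seen. Among gene groups not described above, blood vessel genes moved little. Of 14 endothelial genes 4 fell in delEx44 against WT at 4 weeks (Ptprb, a vessel phosphatase, 93.2 against 137 CPM, log2 −0.55), 0 after running and 2 at 18 months (Flt1, a VEGF receptor, 94 against 144, −0.611), and the list passed at no stage (adjusted p = 0.29, 0.75 and 0.21). Smooth muscle and pericyte genes had 1 rise and 6 falls in 13 at 4 weeks (Abcc9 220 against 397 CPM, −0.851), 3 falls after running and 2 rises and 4 falls at 18 months (Abcc9 309 against 542, −0.812).

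Among p53 and senescence genes 7 of 19 rose and 4 fell in delEx44 at 4 weeks (Ccng1 986 against 1810 CPM, −0.872), and 8 of 18 rose and 3 fell at 18 months (Sesn1 29.5 against 63.1, −1.10; list adjusted p = 0.46). Oxidative stress genes had 9 rises and 9 falls in 23 at 4 weeks (Cyba 40.1 against 11 CPM, 1.86) and 11 rises and 2 falls at 18 months (Sod2 248 against 440, −0.83), and the list passed at neither stage. Unfolded protein response genes passed as a list at 18 months, with 14 rises and 3 falls in 24 (Manf 36.5 against 18.9 CPM, 0.949; Xbp1 0.823; adjusted p = 0.011, and adjusted p = 0.34 with an estimated correlation).

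WT run replicate 1 had almost no Y-linked transcript, with 1 count of Ddx3y, 2 of Eif2s3y and 0 of Kdm5d and Uty. Xist was at 0.148 CPM, which goes against a female mouse with 2 X chromosomes. The other 23 libraries all had Y-linked transcripts, with Xist at 0 to 0.253 CPM, and the strand setting is not given. Whether Xist would have been counted thus could not be checked, and such a female was not excluded. A female with 1 X chromosome is open as well. Y-linked genes missed by the counting were excluded, since these genes were at 16.7 CPM or more in the other 23 libraries. Loss of the Y chromosome in the mouse or the sample may be a cause, but the mean ratio of the 4 X-linked partners to the other WT run library, 1, is the value any mouse with 1 X chromosome would give, so it cannot be told apart from other causes. No biological explanation given by the design was tested.

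Splits of 6 libraries into 3 and 3 are too few (10) for a share under 0.05. Fitted alone, the real split gave 6958 genes for delEx44 against WT at 4 weeks, 6978 for corrected against delEx44 and 0 for corrected against WT, and at 18 months 8626, 5353 and 16, with 0 in the highest other split of each. As many as the real split were reached in 1 of the 10 splits, the real one itself, and in 10 of 10 for corrected against WT at 4 weeks, where edgeR with all 15 libraries had 1497 genes at an unadjusted p under 0.05, DESeq2 called 220 and limma-voom 0.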
